A study of Drosophila melanogaster with 2 samples.

How the data were processed

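Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used, per the labels, to map dmrt93B in whole wandering larvae of the last instar of Drosophila melanogaster, with males and females pooled. The line carried a transgene in which GFP is fused to the C-terminal end of dmrt93B. Both samples form a single group, dmrt93B-GFP, with 2 biological replicates, and no other group was analysed here. The description of each sample calls it an input control, whereas its title, assay name, antibody label and separately named control describe a transcription factor ChIP; the samples were grouped by the antibody label, and the conflict remains open. Chromatin was sheared by sonication, per the labels.

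Per the labels, coordinates are on the dm6 build. The authors deposited 1 relaxed peak list per replicate, 1 relaxed list for the pooled replicates and 1 optimal list past an irreproducible discovery rate (IDR) threshold. Each relaxed list held exactly 30000 entries and the optimal list held 4159. Text deposited with the samples names the same control file for both replicate lists. The aligner, the peak caller, the IDR threshold and the read depth are not given in the sources used here, and the control library was not analysed here. The first value used is the signal of each peak, a peak strength written by the authors' caller, which was used only to rank or describe peaks within a list. The second is the −log10 q value of each peak in the deposited lists, which reached its ceiling of 3.91 in 97.2% of the optimal peaks and was therefore not used for ranking. All 4159 optimal peaks were the 4159 strongest pooled peaks by signal. In the optimal list 60 entries shared an interval with another entry and differed in summit, so peaks were counted by summit. Because depth is unknown, intervals on shares cover counting error only.

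Summits were compared with the Ensembl annotation, release 115, and with the NCBI Release 6 sequence, both in dm6 coordinates; every peak lay on arm 2L, 2R, 3L, 3R, 4 or X. The optimal list was the main set, and the 4159 strongest peaks of each replicate list gave the values per replicate. Lists of equal length were used so that list length could not differ. Summits within 200 bp were taken as shared. A promoter summit lay within 500 bp of an annotated transcription start site (TSS), and the remaining summits were assigned in the order 5' UTR, coding exon, 3' UTR, other exon, intron and intergenic. Chance levels came from 1000 random placements of the summits within their own arm. The tests for overlap, promoter share, TSSs on both strands and tagged locus were one-sided, and all other tests were two-sided. The X chromosome was compared with the autosomes by an exact binomial test.

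Motifs were searched on both strands in windows of 101 bp centred on the summit and, as control, in 1 of the 2 windows centred 500 bp away, chosen at random with a fixed seed, using an exact sign test of discordant pairs. The 19 motifs, including the backwards reading of both DM-domain sites, and all 2080 6-mers were adjusted separately by the Benjamini-Hochberg method. The 33 gene lists were tested with Fisher's exact test against the 13945 protein-coding genes on these arms and adjusted over the lists; 738 of 766 list symbols matched the annotation and the other 28 were left out. Differences of median signal used 100000 permutations. IDR was also fitted anew to the replicate lists, as a copula mixture, with a threshold of 0.05.

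Designs, motifs, gene lists and alternatives were fixed before the data were examined, except where stated. Peaks and genes were named by a fixed rule: the 20 strongest optimal peaks also found among the strongest peaks of both replicates, the optimal peaks within 25 kb of dmrt93B, the listed genes with the strongest promoter peaks (2 to 4 per list), the 6 sequences with the smallest p, and the DM-domain genes. Names outside this rule are marked as chosen after their values were seen. Alternatives changed the overlap criterion, the TSS window, the background, the motif control and window, the list strength and the replicate used. Weak pooled peaks, those from rank 8319 onward, served as a further background.

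The scripts were tested on simulated data. With nothing planted, 0 of 2080 6-mers were called, and 3 of 3 planted 6-mers were recovered together with 37 others, a count that includes shifted copies of the planted ones. Of 500 lists of 20 genes simulated with 1 in 2 members bound 437 were recovered, and 10 unaltered lists were called. Lists of other sizes or with weaker binding were not simulated. The IDR fit recovered 3309 of 3961 reproducible pairs and called 155 others. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.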

Results

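Binding of dmrt93B, a DM-domain protein of the family that includes the sex-determination factor Doublesex, was profiled by ChIP-seq in whole wandering larvae carrying a GFP-tagged copy of the protein. The data comprised 2 biological replicates of 1 group, each with a deposited list of 30000 relaxed peaks, and a pooled optimal list of 4159 peaks. Sample descriptions label these libraries as input controls, in conflict with the antibody label, and the values are given for libraries labelled as dmrt93B ChIP. The read depth is unknown, and the lists do not show why a peak is absent from one of them. Where 1 value per replicate is averaged, the SD measures the spread of 2 samples.

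The same regions led both replicates, among them the promoters of Ugalt, a UDP-galactose transporter gene, and of the chromatin genes ph-p and Chro. Of the 4159 optimal summits, 3486 (83.8%, 95% Wilson interval 82.7 to 84.9) lay within 200 bp of one of the 4159 strongest summits of replicate 1. For replicate 2 the count was 3397 (81.7%, interval 80.5 to 82.8), and 2824 (67.9%, interval 66.5 to 69.3) were found in both. Random placement gave 0.769% ± 0.139 (SD over 1000 placements) for both, with a one-sided permutation p of 0.001, the smallest that 1000 placements can give. The optimal list was itself selected from these replicates, so part of this overlap is built in. Directly between the replicates, 2839 of the 4159 strongest replicate 1 summits (68.3%, interval 66.8 to 69.7) lay within 200 bp of one of the 4159 strongest of replicate 2, where the highest of 20 random placements, added after seeing the data, gave 1.59%. Across the 3614 optimal peaks with an entry in both full lists, the signal ranks of the replicates had a Spearman rho of 0.819; these are peaks within 1 pair of libraries, not independent replicates. A separate IDR fit passed 3977 peaks, of which 83.0% lay within 200 bp of an optimal summit. The lists were unequal in what they missed: 529 optimal peaks had no entry within 200 bp in the full list of replicate 1. For replicate 2 the count was 17. Entries farther away were not counted.

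The 20 strongest optimal peaks were all among the strongest of both replicates, ranking no lower than 21 in replicate 1 and 31 in replicate 2, and 12 of them were promoter peaks. The strongest, with a signal of 4440 in the authors' units, had its summit at X position 2703898 (peak 2703672 to 2704104), 46 bp upstream of a TSS of Ugalt (FBgn0024994). The next lay at 3L position 19590622 (peak 19590398 to 19590832), 98 bp upstream of CG14100 (FBgn0036889), with a signal of 4282. The peak at rank 3, at 2L position 481057 (480873 to 481297), lay in an intron of ush, which encodes a GATA cofactor, and its nearest TSS was that of cbt (FBgn0043364). CG11050 and CG32772 held intronic peaks at ranks 4 and 5, and the peak at rank 6 lay in an exon of the non-coding gene lncRNA:Vinr, nearest to lncRNA:CR44619. Promoter peaks followed at PNPase, CG1888, ph-p and Chro, at ranks 7 to 10. ph-p encodes a Polycomb group protein and Chro a chromodomain protein of chromosome interbands. Intronic peaks lay in CG32486 (nearest TSS CG16753), Adf1, CG4496 and the overlapping HmgZ and HmgD genes, which encode HMG-box DNA-binding proteins. The remaining promoter peaks in this set were at mRpL41, a mitochondrial ribosomal protein gene, CG5611, Tcs5, Art3, the small heat shock gene Hsp27 (3L position 9383903, signal 1990) and the adaptor gene Shc.

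Summits were concentrated at promoters and nearly absent from coding exons. Promoters held 1634 of 4159 summits (39.3%, interval 37.8 to 40.8), 2.93 times the 13.4% ± 0.544 (SD) of random placement (one-sided permutation p = 0.001, the smallest possible). Coding exons held 8 summits (0.192%) against 13.7% at random, 3' UTRs held 0.553% against 4.46%, 5' UTRs 0.385% against 0.788%, and intergenic sequence 18.1% against 27.3%. Each of these classes had a Benjamini-Hochberg adjusted permutation p of 0.0028, the smallest these placements allow. Introns, with 40.4% against 39.6% at random (adjusted permutation p = 0.262), and other exons, with 1.01% against 0.765% (adjusted p = 0.112), did not pass. The promoter share of the strongest peaks was 32.4% in replicate 1 and 48.2% in replicate 2 (40.3% ± 11.2, SD, n = 2), so the excess over random placement was larger than the spread between replicates while its size was uncertain. The weak pooled peaks had 14.2% of summits at promoters (Fisher's exact test against the optimal list, p = 2.58e-274).

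**Figure D1:**
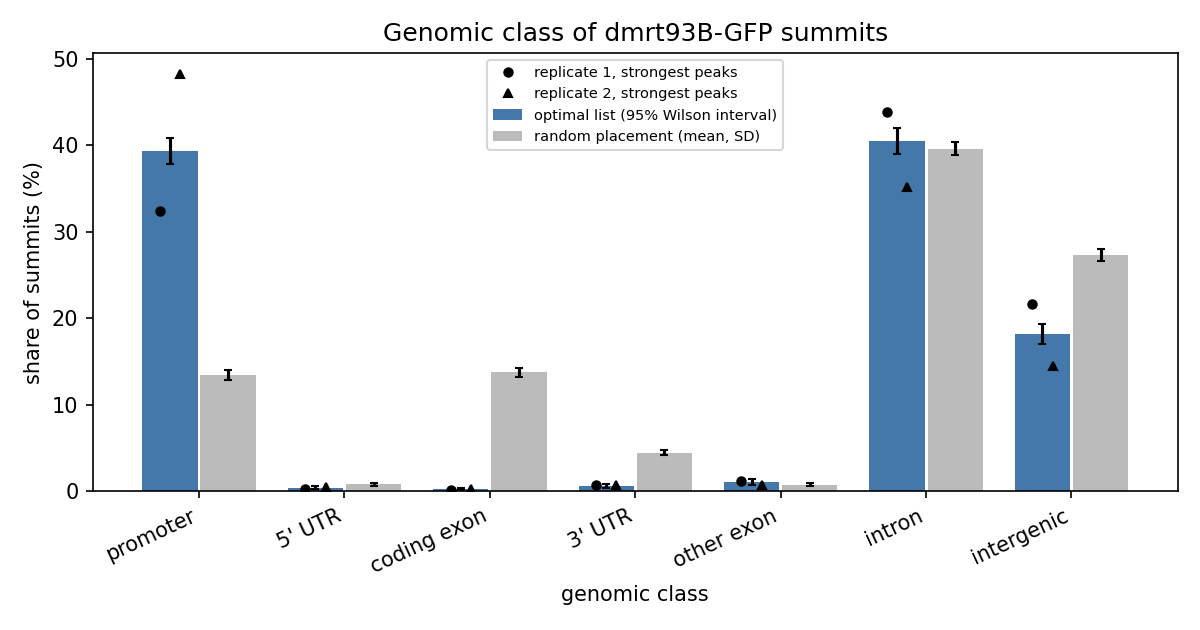
Share of summits (%, vertical axis) in each genomic class; blue bars give the optimal list with 95% Wilson intervals, grey bars the mean and SD of random placement, and black circles and triangles the strongest peaks of replicates 1 and 2. Promoters hold 39.3% of optimal summits against 13.4% at random, with the replicates at 32.4% and 48.2%, and coding exons hold 0.192% against 13.7%.

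Promoter summits lay mostly just upstream of the start site: 1376 of 1634 (84.2%) were upstream of the nearest TSS, with a median position of -132.5 bp (quartiles -235 and -52). TSSs on both strands lay within 500 bp of 550 of them (33.7%). Random placements that fell in promoters gave 11.9% ± 1.34 (SD, one-sided permutation p = 0.01, the smallest that 100 placements allow). This count was made after the class shares were seen. The random positions were not matched on side or distance from the TSS, so part of the excess may follow from the upstream position. Promoter peaks also had a higher signal within the optimal list, with a median of 252 against 196 for all other peaks (difference 56.4, permutation p = 1e-05, the smallest possible). The promoter share was 53.8% in the 1040 strongest optimal peaks and 30.4% in the 1039 weakest.

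Peaks were denser on the X chromosome than on the autosomes. The X carried 858 peaks, 36.4 per Mb, against 33.1 on 3L, 31.9 on 2L, 29.8 on 3R, 26.1 on 2R and 5.93 on chromosome 4, which held 8 peaks. The X to autosome ratio of density was 1.22 (95% exact interval 1.13 to 1.31, exact binomial p = 4.32e-07). It was 1.15 in replicate 1 and 1.21 in replicate 2 (1.18 ± 0.0474, SD, n = 2). Per annotated TSS the ratio was 1.32, and in the weak pooled peaks the ratio per length was 0.918 (interval 0.885 to 0.951). The X did not stand apart from every arm, since in replicate 1 it had 34.7 peaks per Mb and 3L had 34.6. Autosomal arms also differed from one another. The exact test and its interval treat peaks as independent, although some genes held many of them.

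Genes for cytosolic ribosomal proteins, the protein components of the ribosome, had promoter peaks far more often than other genes. A promoter peak was found at 55 of 68 of them (80.9%, interval 70.0 to 88.5), against 1821 of all 13945 protein-coding genes (13.1%), with Fisher's exact test giving an odds ratio of 29.0 and an adjusted p of 2.11e-35. The count was 36 of 68 in replicate 1 and 61 of 68 in replicate 2, and the list passed in each. The strongest were RpS27 (3R position 25247532, signal 1639), RpL7 (2L position 10201033, signal 1355), RpL32 (3R position 30046238, signal 1020) and RpS28b (X position 9554566, signal 881), with summits 18, 77 and 57 bp upstream of the TSS for RpS27, RpL32 and RpS28b and 29 bp downstream for RpL7. Peaks missing from the list of replicate 1 covered 19 of these genes, and 37 had a promoter peak when only peaks entered in both replicate lists were kept (Fisher's exact test, adjusted p = 4.19e-19), a restriction chosen after seeing the data.

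Chromatin regulators were the other list to pass, with 12 of 37 genes (32.4%, interval 19.6 to 48.5, odds ratio 3.21, Fisher's exact test, adjusted p = 0.031). The counts were 10 in replicate 1 and 17 in replicate 2. The 2 lists that passed share a peak, named here after its values were seen. Its summit, at 2L position 9967304, lay 75 bp upstream of Dref among the chromatin regulators and 9 bp upstream of RpL13. The optimal list was not tested without it. ph-p had a signal of 2287, Chro 2256, brm, which encodes the ATPase of the SWI/SNF-type remodelling complex, 1305, and the insulator gene Cp190 1035. This call ended when genes were matched on their number of TSSs (5.87 genes expected in random lists, adjusted permutation p = 0.153), with a TSS window of 1000 bp (Fisher's exact test, adjusted p = 0.0668), and when only peaks entered in both replicate lists were kept (9 genes, adjusted p = 0.112).

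No other list passed the adjustment, although 9 of 33 had an unadjusted p under 0.05. Glycolysis genes had peaks at 5 of 13 promoters (Fisher's exact test, adjusted p = 0.158). Signals were 1333 at Gapdh2, 1176 at Eno and 1102 at Hex-A. For the whole optimal list, random lists matched on the number of TSSs had 3.20 such genes (adjusted permutation p = 0.836). In the 2079 strongest peaks the glycolysis list passed, with the same count of 5 (Fisher's exact test, adjusted p = 0.0343). Those peaks were not tested against matched lists. Ecdysone response genes had 6 of 19 (E23 and Eip75B strongest, Fisher's exact test, adjusted p = 0.158), and replication and cell cycle genes 9 of 35 (Dp and Mcm2, adjusted p = 0.158). Midgut digestive genes had 0 of 29, chemosensory receptor genes 0 of 30, neuropeptide genes 0 of 26 and cuticle protein genes 0 of 28, with the same adjusted p of 0.158. Imaginal disc patterning genes had 0 of 25, yolk and chorion genes 0 of 13, and Hox and head homeotic genes 0 of 8. Oxidative phosphorylation genes (5 of 38, led by blw and ND-51) and proteasome subunit genes (4 of 32, Rpn5 and Prosbeta2) were close to the share of all genes.

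Among developmental and tissue lists, peaks were found at 5 of 20 genes of the Notch pathway list (E(spl)m3-HLH and E(spl)m7-HLH), 8 of 39 signalling genes (spi and aos), 4 of 14 fat body and larval serum genes (bmm and Apoltp), 4 of 18 heat shock genes (Hsp27 and Hsp83), 3 of 16 gut factors (bowl and fkh), 3 of 19 tracheal and epithelial genes (par-6 and grh), 3 of 20 muscle structural genes (Msp300 and Tm1), 2 of 14 glial genes (moody and Gli) and 2 of 17 head and brain patterning factors (cnc and so). A single gene had a promoter peak in the lists for synaptic function (elav), immune effectors (PGRP-LB), neuroblast factors (grh), testis and germ line (stwl), ecdysteroid synthesis (shd), bHLH factors (Fer2), muscle factors (tin), haemocytes (PPO3) and salivary glue (fkh). None of these lists passed, with adjusted p from 0.297 to 1.

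**Figure D2:**
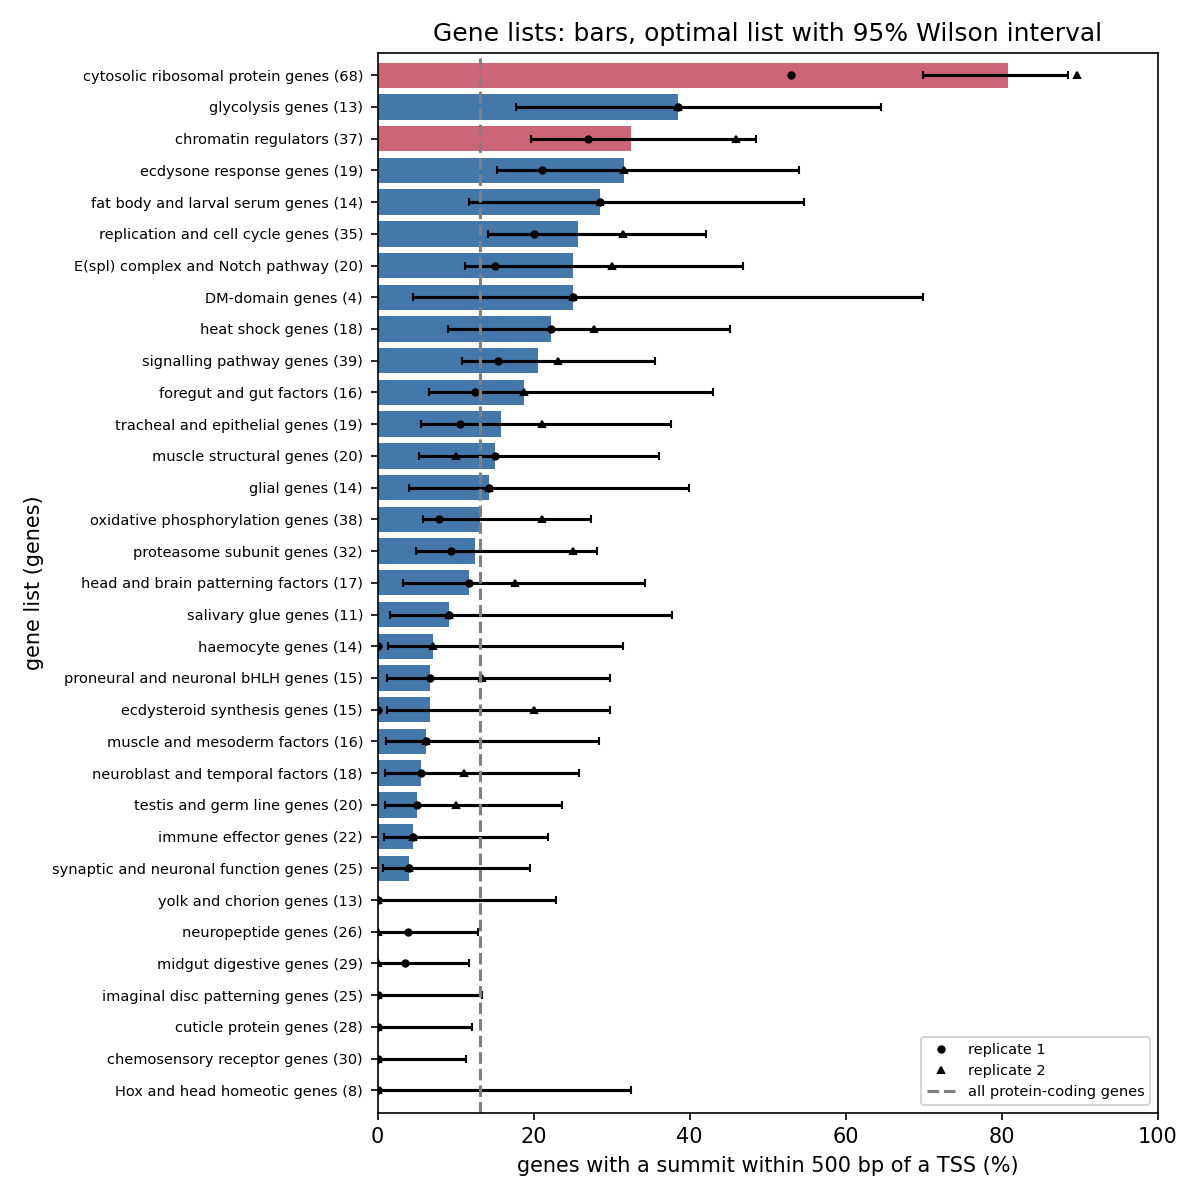
Share of genes (%, horizontal axis) with a summit within 500 bp of a TSS for each of the 33 gene lists, with the number of genes in parentheses; bars give the optimal list with 95% Wilson intervals, red for lists past the adjusted threshold, black circles and triangles the strongest peaks of replicates 1 and 2, and the dashed line all protein-coding genes (13.1%). Cytosolic ribosomal protein genes reach 80.9% and chromatin regulators 32.4%, and 7 lists have no gene with a promoter peak.

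The tagged gene itself showed no concentration of peaks. No optimal summit lay within 25 kb of dmrt93B (FBgn0038851, 3R 21074007 to 21076798, plus strand), where windows of the same length on 3R held 1.57 ± 2.11 (SD, one-sided permutation p = 1). The nearest optimal summit was 56358 bp away. In the full lists of 30000 entries, the pooled list had 1 summit in the window against 11.9 ± 8.06, replicate 1 had 0 against 12.8 ± 7.84 and replicate 2 had 11 against 10.7 ± 9.90 (SD over 1000 windows; one-sided permutation p of 0.9, 1 and 0.44). Of the 4 DM-domain genes, dsx (3R 7924323 to 7967408) had a promoter peak with its summit at position 7963188, 402 bp upstream of a TSS, and a signal of 266, and a promoter peak was found in both replicates. dmrt11E and dmrt99B had no optimal promoter peak, with the nearest summits 3074 and 17049 bp from the gene.

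DM-domain sites were slightly more frequent at summits than beside them, and so were the same sites read backwards. ACAWTGT or TGTATCA, 2 sites fixed beforehand, occurred in 140 of 4159 summit windows (3.37%, interval 2.86 to 3.96) and in 2.48% of flank windows (ratio 1.36, exact sign test p = 0.0197). In the 2079 strongest peaks the call ended (ratio 1.05, exact p = 0.859). In the replicates the share was 2.92% ± 0.153 at summits and 2.13% ± 0.119 in flanks (SD, n = 2), and the exact test passed in replicate 1 (p = 0.00487) and not in replicate 2 (p = 0.0935). The backwards controls occurred in 3.01% of summit windows and 1.30% of flanks (ratio 2.31, exact p = 5.64e-08). With this choice of flanks the DM-domain sites rose less than the backwards ones (Fisher's exact test on the discordant windows, odds ratio 0.565, p = 0.00713), but over 100 further choices, made after seeing the data, the odds ratio ran from 0.51 to 0.965 and passed the exact test in only 25, so the difference was not settled. Against dinucleotide-shuffled copies of the summit windows the DM-domain sites had a ratio of 0.927 (exact p = 0.551) and the backwards sites 0.919 (exact p = 0.528). Peaks with a DM-domain site did not differ detectably in signal from those without (medians 201 and 217, permutation p = 0.302).

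Of the other motifs, the homeodomain site TAATTA was in 10.8% of summits against 5.99% of flanks (exact sign test, adjusted p = 2.37e-14). The DRE site, bound by the promoter factor Dref, was in 0.986% against 0.289% (ratio 3.42, exact test, adjusted p = 0.000194), with 0.793% in replicate 1 (ratio 4.13) and 1.76% in replicate 2 (ratio 10.4), and Motif 1 in 0.697% against 0.216% (adjusted p = 0.00227). The CA repeat (1.01% against 3.70%, exact test, adjusted p = 4.07e-15), the GC box (1.30% against 3.99%, adjusted p = 6.60e-14) and the GAGA repeat (0.842% against 2.77%, adjusted p = 6.31e-11) were less frequent at summits. In all, 12 of 19 motifs passed, among them both backwards controls (exact test, adjusted p = 4.96e-05 and 0.0019) but neither DM-domain site alone (adjusted p = 0.266 for ACAWTGT and 0.0727 for TGTATCA). This contrast rests on 1 choice of flank. TGTATCA and its backwards reading were equal at summits (1.32%) and over both flanks averaged (0.709%). For ACAWTGT the flank average was 1.36% against 2.04% at summits, and for its backwards reading 0.577% against 1.73%. Against dinucleotide-shuffled windows, a control added after seeing the data, 5 motifs passed: DRE (ratio 6.83, exact test, adjusted p = 1.68e-06) and Motif 1 (ratio 14.5, adjusted p = 2.93e-06) in the same direction as against flanks, and TAATTA (ratio 0.852, adjusted p = 0.0242), the CA repeat (ratio 7, adjusted p = 8.37e-07) and the CAGCTG E-box (ratio 2.18, adjusted p = 7.09e-06) in the opposite one. The shuffled copies were of summit windows only, so these ratios do not compare summits with flanks. Among 2080 6-mers, 514 were more and 1007 less frequent at summits than in flanks. All 36 6-mers made only of A and T were among those more frequent. TTAAAA was in 33.8% of summits against 13.4% of flanks (exact sign test, adjusted p = 6.03e-100), and AAATAT, ATATTA, ATTTTA, AATATA and ATTTAA followed.

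Summit sequence was AT-rich, a measure chosen after the 6-mers were seen. The 101 bp at optimal summits had a GC content of 32.96% against 43.7% in the flanks and 42.2% in the genome. The replicates had 33.5% ± 0.938 at summits and 43.9% ± 0.298 in flanks (SD, n = 2), a difference larger than the spread between them. Promoter summits had 33.2% and summits outside promoters 32.8%, whereas weak pooled summits had 43.3%. Promoters of genes without a promoter peak, sampled at the same distances from the TSS, had 40.1%.

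**Figure D3:**
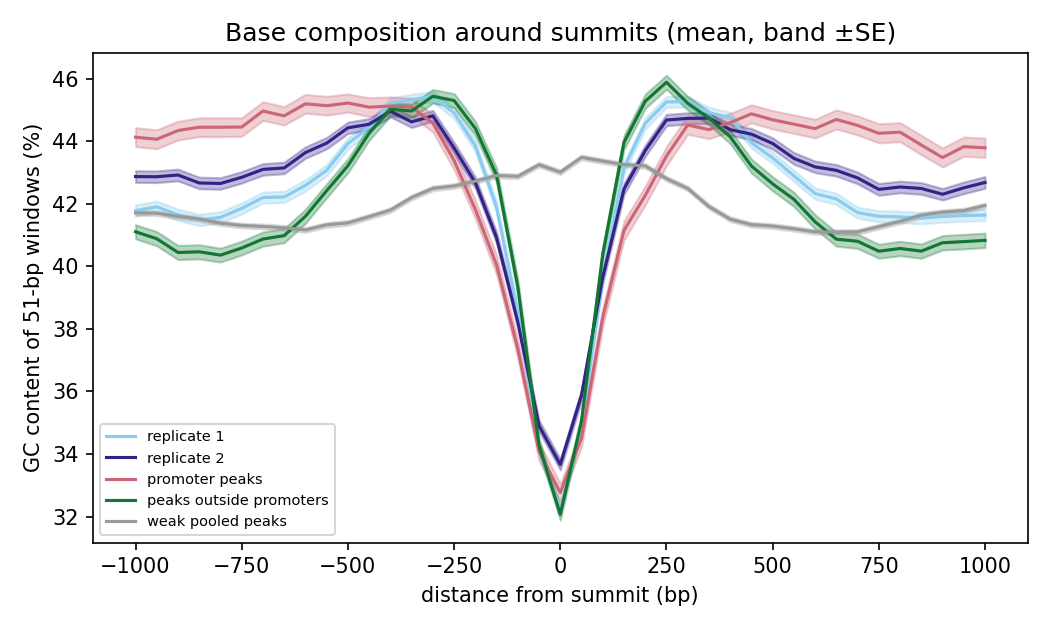
Mean GC content (%, vertical axis) of 51-bp windows against distance from the summit (bp, horizontal axis) for the strongest peaks of each replicate, the promoter and other peaks of the optimal list and the weak pooled peaks, with bands of 1 SE. GC content falls at the summit of all sets except the weak pooled peaks, whose summits have 43.3% GC over 101 bp.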

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

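Alternatives named as added were chosen after seeing the data, and all others beforehand. The share of optimal summits found in both replicates ran from 52.7% with 50% reciprocal overlap to 75.5% in the 2079 strongest peaks, where the highest of 20 random placements for any criterion was 1.80% (placements added). With the optimal list set aside, 68.1% of the strongest replicate 2 peaks lay near those of replicate 1, and 68.3% the other way. The promoter share stayed above random placement under every alternative, with 28.4% for a 250 bp window and 50.4% for 1000 bp, and 32.4% to 48.2% when replicate 2 or replicate 1 was left out. In the 8000 strongest peaks the share was 24.5% in replicate 1 and 44.0% in replicate 2 (added). The X to autosome ratio kept its direction and significance throughout, from 1.15 to 1.32. The ratio of DM-domain sites at summits to flanks was higher at 1.88 for peaks outside promoters, 1.62 and 1.45 with windows of 25 and 100 bp to each side and 1.49 against weak pooled peaks, each with p under 0.05. The backwards sites are not given for these settings, and weak pooled summits had more GC (43.3% against 32.96%). The DM-domain ratio fell to 1.05 in the 2079 strongest peaks (exact sign test, p = 0.859) and ranged from 1.27 to 1.48 with a replicate left out. It turned to 0.927 against dinucleotide-shuffled windows, a control that keeps base composition. It also moved with the random choice of flank: both flanks averaged gave 1.66, and 100 further choices gave 1.36 to 2.09, all with p under 0.05, so the planned choice lay at the low end (added). Of 19 motifs, 12 passed against flanks and 5 against shuffled windows (added), 2 of them in the same direction and 3 in the opposite one. The 2 gene lists that passed became 3 in the 2079 strongest peaks, where glycolysis genes joined, and 6 with whole gene bodies against length-matched lists, where Notch pathway and signalling genes joined as higher and neuropeptide and synaptic genes as lower. They became 1 with lists matched on the number of TSSs and 1 with only peaks entered in both replicate lists (added); the cause was not tested. Ribosomal protein genes passed in each of these settings. With a 1000 bp window the count stayed at 2, but signalling genes took the place of chromatin regulators. The count of summits near dmrt93B was 0 with windows of 10 or 50 kb and 0 to 3 with a replicate left out, never beyond chance. Restriction to the named arms removed no peak and tests nothing. No paired analysis was possible because there is 1 group. Unknown depth limits what an absent peak shows.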

Other observations

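All tests in this part were chosen after the main results were seen, except the match on the number of TSSs, which was an alternative fixed beforehand; the outcomes of the repeat, tRNA, TSS-number and non-promoter GC tests had not been seen when their bounds were written. Of all protein-coding genes, 96 held 5 or more optimal summits. The highest counts were 22 at kirre, 18 at CG1677, 16 each at sbb and shn, 15 at Eip75B, a nuclear receptor gene, 13 at CG12535 and 12 each at Mnt and Raf; the replicates gave 23 and 18 at kirre, 15 and 10 at Eip75B and 12 and 8 at Mnt. Among these 96 the densest by length was CG14434, with 6.54 per 10 kb, followed by bowl with 4.83, egh with 4.71, puc with 4.13 and Mnt with 4.02, against 0.311 over the genome. These genes were named for their counts or densities, so no test applies.

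Grouping protein-coding genes by the letters that open their symbols gave 75 families of at least 10 members. Besides RpL (39 of 50; 28 in replicate 1 and 42 in replicate 2) and RpS (24 of 38; 15 and 29), Mediator subunit genes had promoter peaks at 10 of 25 (adjusted p = 0.00593, Fisher's exact test) and mitochondrial small-subunit ribosomal protein genes at 9 of 26 (adjusted p = 0.0315; 7 in replicate 1 and 11 in replicate 2). Those of the large subunit had 8 of 47 (Fisher's exact test, adjusted p = 0.746; 6 in replicate 1 and 17 in replicate 2), and the 2 families were not tested against each other. Cuticle genes of the Cpr family had 0 of 70 (Fisher's exact test, adjusted p = 0.00196), and the chemoreceptor families Gr, Ir and Or had 0 of 60, 0 of 60 and 0 of 59 (adjusted p of 0.00457, 0.00457 and 0.00576). Histone genes (His) had 2 of 115 (Fisher's exact test, adjusted p = 0.000875), most of them in a repeated array, and 24 symbols opening with pre, nearly all annotated segments of mod(mdg4), had 10. Clustered genes share their surroundings, so members of a family are not independent.

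Replicate 1 lacked promoter entries: of the 529 optimal peaks with no entry within 200 bp in its list, 365 (69.0%) were promoter peaks. Of the listed ones 35.0% were (Fisher's exact test, p = 2.02e-49). Rtnl1, Cp190 and RpL28 were among the strongest missing peaks. A gene with a missing peak could still have another replicate 1 entry farther away. The soft-masked share was 1.24 percentage points higher at missing peaks (upper bound 2.24), a small difference in the direction that repeats would give. Missing and listed peaks were not matched on genomic class, so it does not decide whether repeats were the cause. That 99.8% of the missing peaks were listed in replicate 2 says nothing of a mask common to all lists. Such a mask would have removed them from the optimal list too. Of the 4159 strongest replicate 2 peaks 1112 had no replicate 1 entry, against 110 the other way. Of these 1112 peaks, 600 had an entry in the pooled list and 512 had none. A lack of binding signal in replicate 1 stays open. In 3 of 4 equal bins of replicate 2 rank, the 600 had better median pooled ranks than peaks low in the replicate 1 list. However, the comparison peaks numbered 0, 1, 12 and 21, and the 512 had no pooled rank to compare. Handling of the control by the peak caller was not tested, since the control was not analysed here, and no biological explanation was tested.

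AT-rich summits were not accounted for by the 2 DM-domain sites searched, which only 3.40% (117 of 3442, interval 2.84 to 4.06) of the summits with GC below their flanks held; other forms of the site were not searched. Base composition next to start sites was argued against as the whole cause, because the drop outside promoters was 86.4% of that at promoters, and promoters without a peak dropped by 3.74 points against 11.7 at promoter peaks. AT-rich DNA raising the signal by itself stays open: GC was 31.2% in the 1040 strongest and 34.6% in the 1039 weakest optimal summits, and the weak pooled summits, 1.95 points above their flanks, were chosen by low signal and decide nothing. Chromatin accessibility was not analysed here, and no biological explanation other than the DM-domain sites was tested.

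Ribosomal protein promoters stood out from those of proteasome and oxidative phosphorylation genes, which together had peaks at 12.9% (9 of 70). Fisher's exact test against ribosomal protein genes gave p = 2.18e-16. These lists were taken to stand for constitutive expression in general, which was not measured. The number of TSSs per gene was argued against by 11.9 genes expected in matched lists where 55 were found (permutation p = 0.0002, the smallest possible). Of the tRNA genes, 2.07% (6 of 290) had a summit within 500 bp. Many tRNA genes are repeated and reads there may be lost in alignment, so they do not decide whether strong transcription of any kind brings a peak. Among ncRNA genes 198 of 3261 had a summit (6.07%, 1.93 times random placement, permutation p = 0.0198). For snRNA genes the count was 4 of 32 (12.5%, 4.35 times, permutation p = 0.0792). For snoRNA genes it was 10 of 269 (1.30 times, permutation p = 0.614), and neither of these classes passed. The p-values were not adjusted over the classes. All these classes were below the 80.9% of ribosomal protein genes. A contribution from the level of transcription at protein-coding genes stays open, as expression was not analysed here.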
